A study of Mus musculus with 36 samples.

How the data were processed

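RNA was sequenced from hematopoietic stem cells (HSCs) and restricted progenitors (RPs) sorted from bone marrow of C57BL/6 mice with the Vav-driven Cre recombinase, which acts in blood-forming cells. Per the labels, HSCs were sorted as lineage-negative, cKit-positive, Sca1-positive, CD150-positive, CD48-negative cells, and RPs for RNA as CD150-negative, CD48-positive cells of the same lineage-negative, cKit-positive, Sca1-positive compartment. The labels call the replicates biological and describe each as a pool of male and female mice aged 8 weeks, but give pool sizes that differ within the text. The p-values therefore measure the spread between pools, not between single animals. RNA was converted to libraries with a kit for very small amounts of total RNA, per the labels. The study also holds 18 ATAC-seq samples, which were not analysed here.

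The deposited table held raw read counts per Ensembl transcript, with 138835 transcripts and 36 columns of counts. Its name points to counting over exons with a GENCODE mouse annotation. The submitters' processing notes list STAR 2.0.4, HTSeq 0.8.0, edgeR 3.9, BWA, Picard, deepTools, MACS2, Subread, featureCounts and the build mm10. Which of these made the counts, the strand setting, and the treatment of reads on exons shared by several transcripts or genes are not given in the sources used here. Among 19079 transcripts with more than 200 counts, 0 pairs had identical counts in all libraries. Counts of transcripts with shared exons, of near-identical copies and of overlapping or antisense genes are uncertain for this reason.

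Of the 36 columns, 18 matched samples of the study and 18 were not used, because their names matched no sample. HSC columns carry a genotype and a number but no cell type. They were taken as HSCs because the other columns carry the RP name. Numbers in the RP columns did not match the numbers in the sample titles, so RP libraries were assigned to their group only and are named with the letters a to d. These letters follow the order of the columns and pair with nothing. Some column numbers occur in both RP groups, and whether they pair the libraries was not tested. The groups were Control HSC (n = 3), Dnmt3aKO HSC (n = 3), Tet2KO HSC (n = 4), Control RP (n = 4) and Tet2KO RP (n = 4).

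The tests had been planned on counts summed per gene. The sources used here do not pair the transcript identifiers with genes, so every test was run on transcripts. Sums per gene, the gene lists for cell types and pathways, and the levels of Dnmt3a and Tet2 as a check of the genotype labels were not run. A transcript identifier is printed for at most 2 higher and 2 lower transcripts of a comparison. The rule for these, set before the data were examined, took the largest fold changes among transcripts past the threshold with no overlap between the libraries of both groups and a mean CPM of at least 5 (counts per 1000000 of the scaled library size) in the higher group. Its parts that need gene names were not applied, and the number per direction was reduced to 2.

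Transcripts were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 26820 transcripts holding 98.92% of all counts. A further 58447 transcripts had no count in the libraries used. Libraries were scaled with TMM factors, and all 18 libraries entered a quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3 with group as the only term. The 7 comparisons were tested with Benjamini-Hochberg adjustment at 0.05. Levels are TMM-scaled CPM, given as mean ± SD. Folds against a group with no counts are lower bounds, computed against a floor of 3 counts over that group's libraries. With 1 to 3 counts, the ratio is given with its exact 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

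Lists of the 200 most RP-high and the 200 most HSC-high transcripts, ranked by p among those past the threshold, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01) and again with an estimated correlation. Each list was drawn, where the design allowed, from libraries outside the comparison tested. Overlaps were set beside the number expected from independent lists. Correlations of fold changes against the shared Control HSC libraries were set beside 20 simulations of unchanged groups. The medians of the RP-high and HSC-high lists were set beside 20 simulations with differences between cell types and none between genotypes. Detection was compared after reducing each library, by calculation, to 3721009 counts, the smallest total, with exact two-sided permutation tests. Libraries of the same group had Spearman correlations of 0.728 to 0.863 and differed by at least 7.87 chi-square units per degree of freedom, so each was counted as a separate sample.

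The count test was tested on simulated data drawn from the means and library sizes of these libraries, with 200 changed transcripts in each mutant group. For Dnmt3aKO against Control HSCs, with 26164 transcripts tested, it recovered 9 of 100 transcripts changed 4-fold and 31 of 100 changed 16-fold. For Tet2KO against Control HSCs it recovered 9 and 49 of 100, and for Tet2KO against Control RPs 18 and 56 of 100. Calls of unchanged transcripts were 2.44%, 4.92% and 5.13% of all calls in these comparisons. Without the filter, they were 23.68%, 16.84% and 22.02%, and with DESeq2 1.42.0 they were 19.78%, 24.22% and 22.56%. The simulated counts used edgeR's own estimates of spread, and fold changes in HSCs spread less in such simulations than in the data. These rates may therefore differ in the data, and the comparison of methods may favour edgeR. The set test found a list of 185 transcripts shifted by 0.5 on the log2 scale in simulated Dnmt3aKO HSCs to be higher, and called 0 of 100 unchanged lists. Simulated transcripts were drawn independently of each other and the unchanged lists at random. The rate of false calls for lists of transcripts that vary together was therefore not tested.

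Alternatives tried were RLE size factors, no filter on low counts, DESeq2, a fit of only the groups compared, lists of 100 and 500 transcripts, an estimated correlation in the set test, and leaving out each library. Where fewer than 500 passed the threshold, the list held all of them. These were 208 RP-high and 277 HSC-high transcripts from Tet2KO cells, and 215 and 294 from Control cells. A fit of the HSC libraries alone, a replicate block within it, and a fit without the 3 HSC libraries numbered 4 were added after seeing the data, as were the simulations of the lists.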

Results

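Transcripts were counted in HSCs from Control, Dnmt3aKO and Tet2KO mice and in RPs from Control and Tet2KO mice, to ask how loss of either DNA-methylation regulator changes gene expression in stem cells. DNMT3A adds methyl groups to cytosine, and TET2 oxidises them. Control HSCs had 3 libraries of 4949973 to 6453611 counts, Dnmt3aKO HSCs 3 of 4625653 to 7209032, and Tet2KO HSCs 4 of 5486287 to 9366421. Control RPs had 4 libraries of 3721009 to 7649318 counts and Tet2KO RPs 4 of 4210597 to 6628078. After filtering, 26820 transcripts were tested. The files do not pair transcript identifiers with gene names, so transcripts are given by identifier.

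Outside the HSC libraries numbered 4, the second principal component separated the cell types and the first separated Tet2KO HSCs from the other HSCs. On the second component the 8 RP libraries lay between 15.72 and 65.11 and the 7 HSC libraries not numbered 4 between -83.7 and -40.79, while Control, Dnmt3aKO and Tet2KO HSC libraries numbered 4 lay at 39.94, 99.21 and -1.2. On the first component Tet2KO HSC replicates 1 to 3 lay between -40.93 and -27.35, and the Control and Dnmt3aKO HSC libraries not numbered 4 between 35.89 and 69.98. Control, Dnmt3aKO and Tet2KO HSC libraries numbered 4 lay apart from the other HSC libraries of their genotype, at 124.8, 214 and 90.62 on the first component. At equal depth these 3 libraries held 31276, 25496 and 33540 transcripts, the fewest of each group. Every library with a positive value on the first component held at most 38514 transcripts at equal depth. Every library with a negative value held at least 39880. The first component therefore does not tell the Tet2KO genotype apart from the number of transcripts detected.

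**Figure D1:**
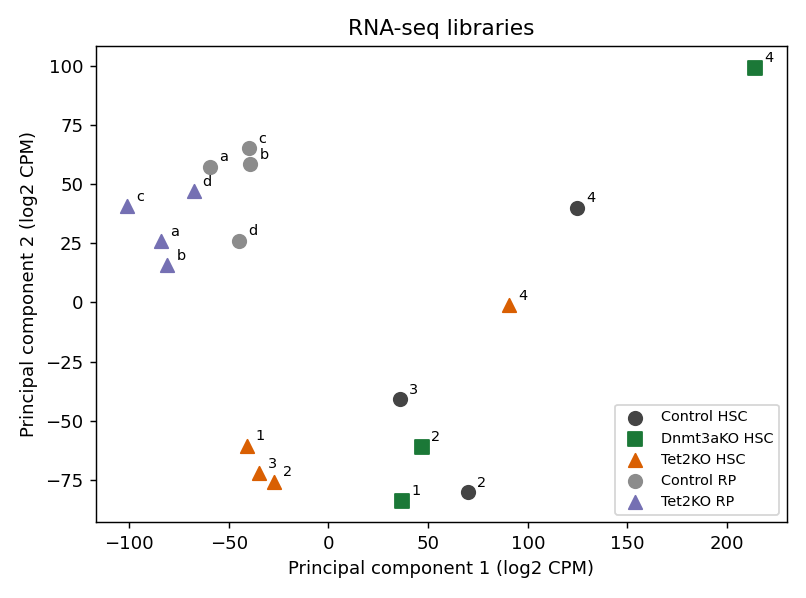
Principal components 1 and 2 of log2 CPM for the 18 libraries. Each point is a library, coloured by group and marked with its number or letter; the HSC libraries numbered 4 lie to the right of the other HSC libraries.

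Control RPs and Control HSCs were compared to define the difference between the cell types. Of the transcripts tested, 215 were higher and 294 lower in Control RPs, 509 in all, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least 2-fold differences made up 500 of these, with transcripts that had no count in a group set to the floor. ENSMUST00000102802.9 was at 32.6 ± 5.2 CPM (SD, n = 4) in Control RPs and had no count in Control HSCs (n = 3), at least 183.3-fold higher in RPs (adjusted p = 6.21e-04, edgeR). ENSMUST00000031005.10 had no count in Control RPs and was at 5.64 ± 2.04 CPM in Control HSCs, at least 39.27-fold lower in RPs (adjusted p = 0.00164, edgeR). Leaving out Control HSC replicate 2 reduced the count to 264 transcripts.

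Tet2KO RPs and Tet2KO HSCs differed in 485 transcripts, 208 higher and 277 lower in RPs. Leaving out Tet2KO RP replicate d reduced the count to 296 transcripts. Of the differences between RPs and HSCs, 267 were called in both genotypes, 93 higher and 174 lower in RPs, against 1.67 and 3.04 expected from independent lists. None was called in opposite directions. Across the tested transcripts, which are not independent replicates, the fold changes of the 2 genotypes had a Pearson correlation of 0.368. ENSMUST00000015460.4 was at 1.15 ± 1.36 CPM in Tet2KO RPs and 106.7 ± 34.9 CPM in Tet2KO HSCs (n = 4 each), a log2 fold change of -6.43 (SE 0.58, adjusted p = 7.09e-06, edgeR).

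Tet2KO HSCs were compared with Control HSCs to find the effect of Tet2 loss in stem cells. In Tet2KO HSCs 36 transcripts were higher and 17 lower, and the 53 all differed at least 2-fold. ENSMUST00000029722.6 fell from 1791 ± 118 CPM (SD, n = 3) in Control HSCs to 29.5 ± 3.1 CPM (n = 4) in Tet2KO HSCs, a log2 fold change of -5.92 (SE 0.25, adjusted p = 4.99e-11, edgeR's quasi-likelihood test). ENSMUST00000117405.1 was at 71.2 ± 34.6 CPM in Tet2KO HSCs and had 3 counts over the Control HSC libraries, a ratio of 362.6 (95% counting interval 123.9 to 1760, adjusted p = 0.00469, edgeR). ENSMUST00000207004.1 had no count in Control HSCs and 7.81 ± 3.62 CPM in Tet2KO HSCs, at least 43.85-fold higher (adjusted p = 0.0434, edgeR), and lost its call in 10 of 14 alternatives. The count depended on the libraries, at 18 without Control HSC replicate 2 and 106 without Tet2KO HSC replicate 4. It was 21 in a fit of only the groups compared, 15 with the HSC libraries alone and 10 with a replicate block on these. DESeq2 called 673 transcripts, of which 53 were shared with edgeR.

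Tet2KO and Control RPs were compared to ask the same question in progenitors. In Tet2KO RPs 25 transcripts were higher and 11 lower, and the 36 all differed at least 2-fold. ENSMUST00000029722.6 fell from 2187 ± 364 CPM (n = 4) in Control RPs to 40.02 ± 9.07 CPM (n = 4) in Tet2KO RPs, a log2 fold change of -5.77 (SE 0.25, adjusted p = 5.19e-11, edgeR). ENSMUST00000161230.2 fell from 130.5 ± 39.4 to 5.58 ± 1.05 CPM (log2 fold change -4.54, SE 0.55, adjusted p = 2.74e-04, edgeR). ENSMUST00000123179.1 was at 6.58 ± 0.53 CPM in Tet2KO RPs with no count in Control RPs, at least 45.77-fold higher (adjusted p = 0.00587, edgeR). ENSMUST00000103446.1 was at 85.4 ± 77.7 CPM in Tet2KO RPs and 0.222 ± 0.174 CPM in Control RPs (log2 fold change 8.37, SE 1.17, adjusted p = 0.00142, edgeR). Its Tet2KO RP replicate a, at 0.4462 CPM, lay at the level of Control RPs, which reached 0.423, and the other 3 lay at 39.64 to 162.4 CPM. Fitting only the 8 RP libraries gave 78 transcripts.

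The effects of Tet2 loss in HSCs and RPs, which share no library, were compared with each other. Both comparisons called 22 transcripts, 13 higher and 9 lower in Tet2KO, against 0.0336 and 0.00697 expected from independent lists, and none in opposite directions. Of these, 12 were at least 16-fold higher and 3 at least 16-fold lower in both cell types, with all-0 groups set to the floor. For 1 of the 12, ENSMUST00000117405.1, Tet2KO RP replicate d was at 0.4874 CPM, within the 0.2115 to 0.5696 CPM of Control RPs. Leaving out Control HSC replicate 3 reduced the shared calls to 14. In Dnmt3aKO HSCs 0 of the 22 were called by edgeR, and 4 had an unadjusted p under 0.05. Of the 53 transcripts called in HSCs, 48 had the same direction in RPs. Across transcripts the fold changes had a Pearson correlation of 0.292 and a Spearman correlation of 0.229. The difference between the Tet2 effects in RPs and HSCs, tested as an interaction, passed the threshold for 0 transcripts in edgeR. At an unadjusted p under 0.05 there were 1435 against 1341 expected by chance, and DESeq2 called 13.

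**Figure D2:**
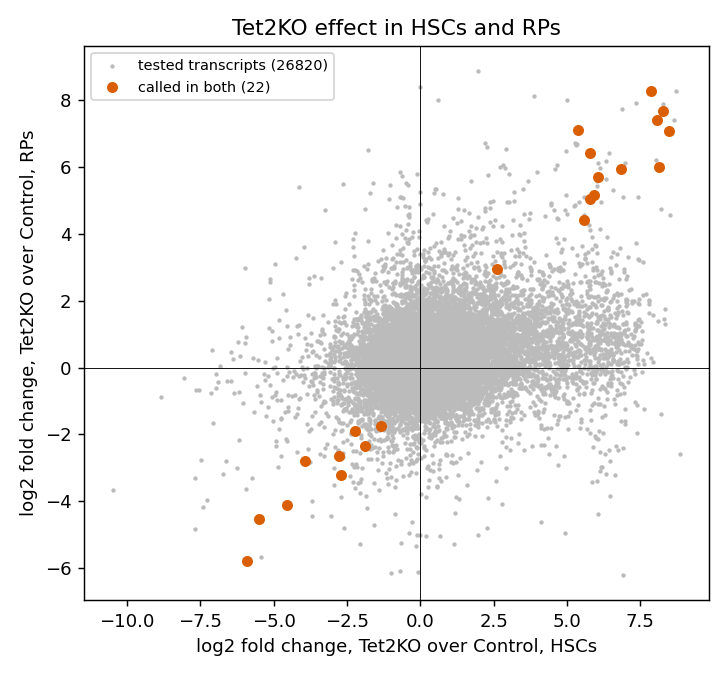
Fitted log2 fold change of Tet2KO over Control in HSCs (horizontal) and RPs (vertical) for the 26820 tested transcripts in grey. The 22 transcripts called in both cell types, in orange, lie in the upper right (13) or the lower left (9).

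Dnmt3aKO HSCs were compared with Control HSCs to find the effect of Dnmt3a loss. In Dnmt3aKO HSCs 1 transcript was higher and 3 were lower by edgeR's quasi-likelihood test. ENSMUST00000121886.7 was at 263.6 ± 93.1 CPM in Dnmt3aKO HSCs and 48.7 ± 23.5 CPM in Control HSCs (n = 3 each), a log2 fold change of 2.44 (SE 0.38, adjusted p = 0.0429, edgeR). It was at 138 ± 35.8 CPM in Tet2KO HSCs, where its difference from Control HSCs missed the threshold (adjusted p = 0.0979, edgeR). ENSMUST00000079237.6 had 1 count over the Dnmt3aKO libraries and 21.6 ± 14.3 CPM in Control HSCs, a ratio of 391.9 (95% counting interval 69.92 to 15520, adjusted p = 2.24e-04, edgeR), and was at 25.9 ± 8.48 CPM in Tet2KO HSCs. ENSMUST00000234467.1 had no count in Dnmt3aKO HSCs and 8.37 ± 4.69 CPM in Control HSCs, at least 49.01-fold lower (adjusted p = 0.0465, edgeR). It was also low in Tet2KO HSCs, at 1.10 ± 0.79 CPM, where its difference from Control HSCs missed the threshold (adjusted p = 0.148, edgeR). Of 13 alternatives the call was lost in 7 for ENSMUST00000121886.7, 3 for ENSMUST00000079237.6 and 9 for ENSMUST00000234467.1. The third lower transcript had a log2 fold change of -5.32 (SE 0.84, adjusted p = 0.0429, edgeR). Fitting only the 6 libraries compared called 0 transcripts in edgeR, and DESeq2 called 174. In the fit of all libraries, edgeR's unadjusted p was under 0.05 for 2079, against 1341 expected by chance. That fit shares its estimate of spread across groups and gave 1024 for Tet2KO against Control RPs, below the number expected. The excess therefore does not by itself show further changes in Dnmt3aKO HSCs. Leaving out Control HSC replicate 3 gave 1 call, and leaving out Dnmt3aKO HSC replicate 4 gave 2, with 1 of the 4 main calls kept in each. The calls also changed where their number held. Without Dnmt3aKO HSC replicate 2 there were 4 calls with 1 main call kept, and without replicate 1 there were 5 with 2 kept. Without Control HSC replicates 2 and 4, there were 4 and 3 calls with 3 and 2 kept.

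Dnmt3aKO and Tet2KO HSCs were then compared directly. In Dnmt3aKO HSCs 12 transcripts were higher and 25 lower than in Tet2KO HSCs. ENSMUST00000029722.6 was at 1737 ± 452 CPM (n = 3) in Dnmt3aKO HSCs and 29.5 ± 3.1 CPM (n = 4) in Tet2KO HSCs (log2 fold change 5.88, SE 0.25, adjusted p = 5.53e-11, edgeR). ENSMUST00000183478.1 had 1 count over the Dnmt3aKO libraries and 54.2 ± 23.8 CPM in Tet2KO HSCs, a ratio of 884.7 (95% counting interval 158.5 to 34960, adjusted p = 2.69e-05, edgeR). The count was 9 without Dnmt3aKO HSC replicate 4 and 63 without Tet2KO HSC replicate 4.

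The Dnmt3aKO and Tet2KO effects in HSCs shared 0 called transcripts, against 0.00134 higher and 0.0019 lower expected from lists of these sizes. Their fold changes had a Pearson correlation of 0.548 across transcripts. In 20 simulations of unchanged groups that share simulated Control HSC libraries, the correlation was 0.535 to 0.56. The simulations kept the sharing of controls but drew new counts for the 3 Control HSC libraries. The covariance was 1.26, against a simulated mean of 0.551. The simulated variance of fold changes was below the observed one in HSCs, at 1.10 against 2.15 for Dnmt3aKO and 0.922 against 2.47 for Tet2KO, so the covariance difference of 0.712 does not measure a shared effect alone. The 3 Control HSC libraries could not be split into parts of at least 2 libraries each, so part of the excess may come from the shared controls.

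Lists of transcripts that separate RPs from HSCs were tested in the mutants. In Dnmt3aKO HSCs, with lists drawn from Tet2KO RPs and HSCs, the 200 RP-high transcripts were lower as a set, with a median log2 fold change of -0.44, 140 below 0 and 49 above (camera, adjusted p = 6.15e-06; adjusted p = 0.189 with an estimated correlation). The other RP-high members had a fold change of 0. RP-high transcripts were chosen for lower levels in HSCs, so some of these fold changes may rest on few counts. The 200 HSC-high transcripts were higher as a set, with a median of 0.14, 132 above 0 and 68 below (camera, adjusted p = 8.09e-04; adjusted p = 0.189 with an estimated correlation). No member of either list was called over all transcripts, and adjusted over the list alone 12 RP-high members were called, 2 higher and 10 lower, and 0 HSC-high members. The 3 HSC libraries numbered 4 held 76.87% of the mean number of transcripts in the other 7 HSC libraries at equal depth. Without Control HSC replicate 4 the RP-high call was lost and its median was -0.06, with 104 below 0 and 82 above (adjusted p = 0.0718). Other fits moved away from 0. The HSC-high median was 0.25 without Control HSC replicate 4, and the RP-high median was -0.73 without Control HSC replicate 2. Without Dnmt3aKO HSC replicate 4 the HSC-high call was lost with a median of 0.13 (adjusted p = 0.563), and without Control HSC replicate 3 with a median of 0.06 (adjusted p = 0.207). Without all 3 HSC libraries numbered 4, both calls were kept at the preset correlation, with medians of -0.43 (camera, adjusted p = 9.81e-07) and 0.17 (camera, adjusted p = 0.0262). That fit compared only Dnmt3aKO HSC replicates 1 and 2 with Control HSC replicates 2 and 3. In 20 simulations with no genotype effect, medians lay between -0.02 and 0.01 for the RP-high list and between -0.09 and 0.07 for the HSC-high list. Fold changes in HSCs spread less in simulations than in the data, and simulated transcripts varied independently, so these ranges may be too narrow.

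In Tet2KO HSCs, with lists from Control RPs and Dnmt3aKO HSCs, which also carry the Dnmt3a genotype, the RP-high list had a median of -0.08 and a mean of 0.105, opposite in sign (camera, lower, adjusted p = 0.0317; adjusted p = 0.348 with an estimated correlation). The HSC-high list had a median of -0.11 and a mean of -0.014 (camera, lower, adjusted p = 0.0193; adjusted p = 0.348 with an estimated correlation). Camera sets each list against all transcripts, whose median was 0.10, and the most abundant of 5 bins of transcripts had a median of -0.09, so these shifts are not set apart from the trend with abundance. The 20 simulations with no genotype effect spread less than the data and drew transcripts independently. Their medians were 0 to 0.12 for the RP-high and -0.03 to 0.14 for the HSC-high list. Over all transcripts 4 RP-high members were called higher and 1 lower, and 1 HSC-high member was called higher. Adjusted over the list alone, 9 RP-high members were called, 6 higher and 3 lower, and 6 HSC-high members, all higher. Without Control HSC replicate 4 neither list was called, at adjusted p = 0.955 for both, and both medians changed sign, to 0.08 and 0.02. The HSC-high median was 0.04 without Tet2KO HSC replicate 3 (adjusted p = 0.623). It moved the other way, to -0.22 without Tet2KO HSC replicate 4 and -0.18 without Control HSC replicate 3. The RP-high median was -0.21 without Control HSC replicate 2. Without all 3 HSC libraries numbered 4, both calls were kept in the same direction at the preset correlation, with medians of -0.12 (camera, adjusted p = 0.0128) and -0.10 (camera, adjusted p = 0.0478).

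In Tet2KO RPs each list shares an RP group with the comparison, so the choice of its members sets a direction with no Tet2 effect, and its camera p alone does not show a change of the list. With lists from Control cells, the RP-high median was -0.19 (camera, adjusted p = 0.00167; adjusted p = 0.14 with an estimated correlation), within the -0.38 to -0.08 of 20 simulations with no genotype effect. The HSC-high median was 0.31 (camera, adjusted p = 3.17e-09; adjusted p = 0.0319 with an estimated correlation), within the simulated 0.07 to 0.32. The same simulations called the RP-high list lower in 19 of 20 and the HSC-high list higher in 19 of 20. With lists from Tet2KO cells, the RP-high median was -0.02 and its mean 0.206 (camera, adjusted p = 0.543), and the simulated medians were 0.09 to 0.38. The HSC-high median was -0.08 (camera, adjusted p = 0.22), with simulated medians of -0.27 to -0.11. The lists from Tet2KO cells lay outside the simulated range, which covers only the spread put into the simulation, with transcripts drawn independently. For the HSC-high list this depended on single libraries. Its median ranged from -0.15 (without Control RP c), inside the simulated range, to 0.05 (without Control RP d). The RP-high median stayed below the simulated range, from -0.14 (without Control RP d) to 0.02 (without Control RP a). For lists from Control cells the medians were -0.33 and 0.48 without Control RP replicate d. The HSC-high median was 0.40, 0.37 and 0.36 without Control RP b, Tet2KO RP a and Control RP a, and fits with 1 library fewer were not simulated.

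**Figure D3:**
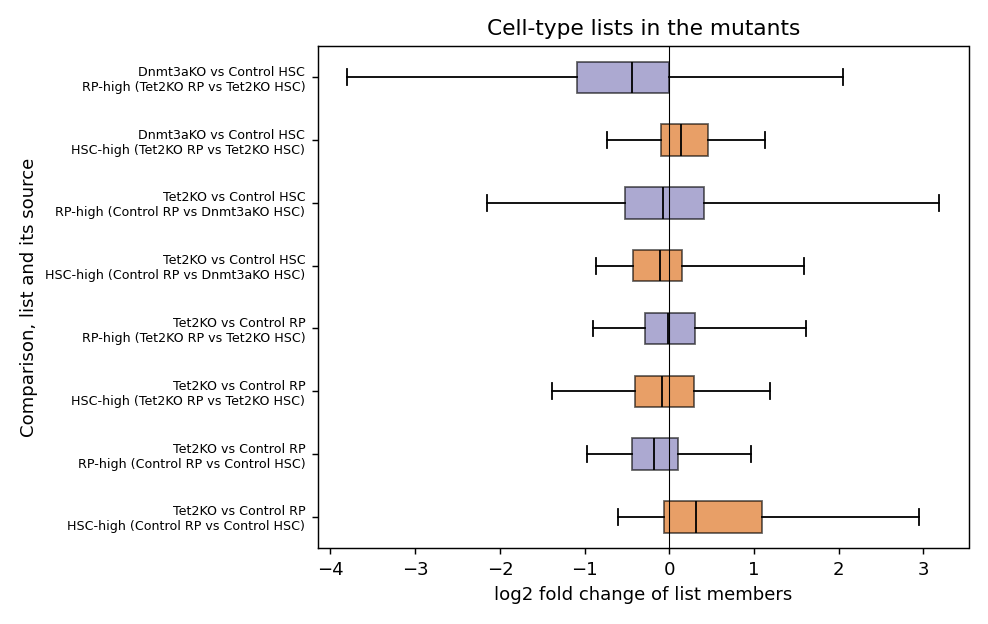
Fitted log2 fold change (horizontal) of 200 RP-high (purple) or HSC-high (orange) transcripts in each mutant comparison, with the source of the list in brackets. Boxes show the quartiles with the median as a line, and whiskers the 5th and 95th percentiles; the RP-high list in Dnmt3aKO HSCs has the lowest median, -0.44 (-0.06 without Control HSC replicate 4), and the HSC-high list from Control cells in Tet2KO RPs the highest, 0.31, within the 0.07 to 0.32 simulated with no genotype effect.

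The number of transcripts detected at equal depth was compared between genotypes. Tet2KO RPs held 43421 transcripts on average and Control RPs 40751, without overlap between the 4 libraries of each (exact two-sided permutation p = 0.0286, the smallest these groups allow; 0.0857 after adjustment over 3 comparisons). Tet2KO HSCs held 40309 and Control HSCs 34100 (exact permutation p = 0.143, adjusted 0.214). Within each number that both share, Tet2KO HSCs held more, at 41473 against 33584 for number 2, 44049 against 37439 for number 3 and 33540 against 31276 for number 4. Tet2KO HSC replicate 1, with no Control library of its number, held 42174. The numbers were not taken to pair the samples, so these values are not a paired test. Dnmt3aKO HSCs held 33639, within the spread of Control HSCs (exact permutation p = 0.9), with more than Control for number 2 (38514 against 33584) and fewer for number 4 (25496 against 31276). With 3 libraries against 3, that test cannot go below 0.1.

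**Figure D4:**
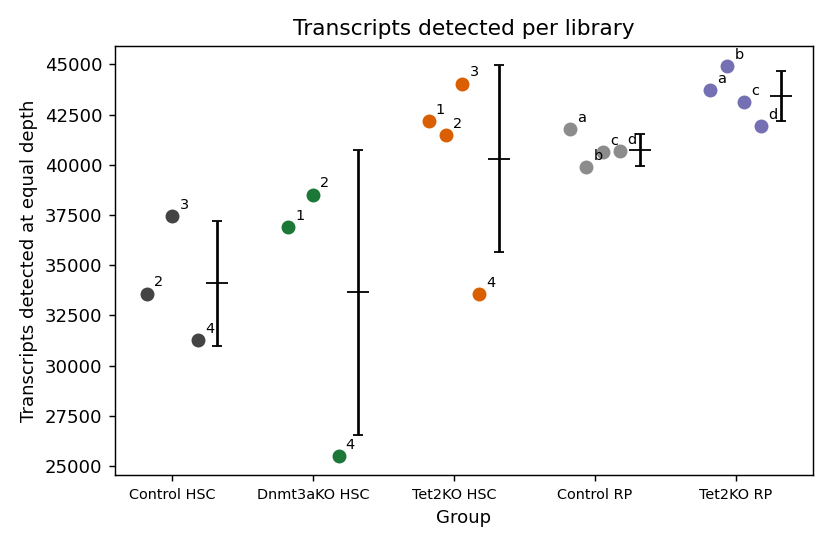
Transcripts with at least 1 count (vertical), after each library was reduced to 3721009 counts, for the 5 groups. Points are libraries marked with their number or letter, and bars show the mean and SD; the axis does not start at 0.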

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

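The tests of chance overlap, of the detection floor, of depth and of shared preparation below were chosen after their results had been seen, as was the split of Dnmt3aKO and Control HSCs. In 31 tests of groups of 4 libraries for a library far from the rest, 5 stood out, where chance gives about 1 in 20. Tet2KO RP replicate d held ENSMUST00000103558.2 at 200.6 CPM, with the other 3 libraries at 0.227 to 1.34 CPM, and it holds 1235 of the transcript's 1244 counts in Tet2KO RPs; without this library the transcript was not tested. In Control RP replicate d the 100 most counted transcripts took 27.6% of counts, against 30.15% to 30.61% in the others. The remaining 3 rest on very few counts beside libraries at 0: ENSMUST00000196194.4 at 0.0922 CPM in Tet2KO HSC replicate 3, ENSMUST00000200235.1 at 0.168 CPM in Tet2KO HSC replicate 1, and ENSMUST00000205228.2 at 0.487 CPM in Tet2KO RP replicate d.

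Other splits of the same libraries, fitted on the groups compared, show where chance can be excluded if libraries of both groups can be exchanged freely. For Tet2KO against Control HSCs the real split called 21 transcripts and the highest of the other splits 2, and 1 of 35 splits, the real one, reached that count. The same held for Dnmt3aKO against Tet2KO HSCs (10 and 1), Tet2KO against Control RPs (78 and 20), Control RPs against HSCs (608 and 1) and Tet2KO RPs against HSCs (415 and 0). Between HSC genotypes the libraries numbered 4 vary together, and exchanging libraries only within a shared number leaves too few splits for a share under 0.05, so chance is excluded there only with the numbers set aside. For Dnmt3aKO against Control HSCs there are 10 splits, too few for a share under 0.05, with 0 called in the real split and 0 in the highest other. For the interaction the real split called 0 transcripts, which each of the 50 splits drawn reaches by construction, so the splits say nothing on chance there. The highest other split, with 38, exchanged the genotype of 6 of the 8 RP libraries and of 2 of the 7 HSC libraries.

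The 22 transcripts called in Tet2KO HSCs and in Tet2KO RPs differed mostly by large folds, with medians of 46.73 in HSCs and 34.57 in RPs when all-0 groups are set to the floor. The list sizes allow 0.0405 shared calls of the same direction by chance, which argues against independent lists. Their median level was 73.8 CPM in the genotype where they are higher, and the lowest was 5.75 CPM. Passing the threshold in both cell types favours such levels, so they do not test noise near the detection floor. A sequence difference carried with the Tet2 line and Tet2 loss itself cannot be told apart, since both go with the genotype and the genes' positions were not used here. The fold change differed between HSCs and RPs at an unadjusted p under 0.05 for 1 of the 22, as the rule set beforehand asks of a strain difference. This decides nothing, because the transcripts were picked for being called alike in both cell types.

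The HSC libraries numbered 4 had fewer transcripts in each of the 3 genotypes. Depth is argued against, since 3 of 3 remained the lowest of their group at equal depth. Without the 100 most counted transcripts of each library, they held 78.02% of the mean of the other 7 HSC libraries, which argues against a few transcripts taking the counts. The lowest correlation of deviations among these libraries was 0.2002, above the 0.139 reached by libraries of different numbers. Libraries that each detect fewer transcripts can deviate alike without a shared preparation, so this correlation does not decide on it. A shared preparation remains a candidate explanation. The labels name no batch, and a difference between the pooled mice was not tested.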

How the results depend on the processing

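The fits of HSC libraries alone, with a replicate block, and without the 3 HSC libraries numbered 4, as well as the library-by-library range of the correlations, shared calls and lists, were added after seeing the data; the cause of a change was not tested unless stated. Order below is Dnmt3aKO over Control HSCs, Tet2KO over Control HSCs, Dnmt3aKO over Tet2KO HSCs, Tet2KO over Control RPs, Control RPs over HSCs, Tet2KO RPs over HSCs, and the interaction. RLE size factors kept every count of transcripts within 1.5 times. With no filter on low counts edgeR called 291, 1001, 752, 241, 1355, 951 and 241 transcripts, and DESeq2 called 174, 673, 536, 117, 1500, 1069 and 13. Both gave more false calls than the main test on simulated data. That simulation used edgeR's estimates of spread, and its fold changes in HSCs spread less than in the data, so these rates may not hold there. Fitting only the groups compared gave 0, 21, 10 and 78 for the first 4. HSC libraries alone gave 0, 15 and 11. Without the 3 HSC libraries numbered 4 Tet2KO over Control gave 96 in HSCs and 69 in RPs.

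Leaving out 1 library gave 1 to 5 transcripts for Dnmt3aKO over Control HSCs. For Tet2KO over Control HSCs it gave 18 (without Control HSC replicate 2), 24 (Control 3), 31 (Control 4), 32 (Tet2KO 1), 35 (Tet2KO 2) and 106 (Tet2KO 4). For Dnmt3aKO over Tet2KO HSCs it gave 9 (Dnmt3aKO 4), 18 (Dnmt3aKO 1), 20 (Dnmt3aKO 2), 11 (Tet2KO 2), 15 (Tet2KO 1), 17 (Tet2KO 3) and 63 (Tet2KO 4). Control RPs over HSCs ranged from 264 (without Control HSC 2) to 493, with 310, 315 and 319 without RP a, c and b and 334 without Control HSC 4. Tet2KO RPs over HSCs ranged from 296 (RP d) to 409, with 312 without HSC 2 and 322 without RP a. Fewer libraries also lower the power of each fit.

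A replicate block on the HSC libraries alone called 0 transcripts for Dnmt3aKO over Control, 10 for Tet2KO over Control and 8 for Dnmt3aKO over Tet2KO. Deviations from group means correlated at 0.2002 to 0.251 for the 3 pairs numbered 4, at 0.0389 to 0.0993 for the other 5 pairs of the same number and at -0.193 to 0.139 for 25 pairs of different numbers. Of the pairs of the same number only those numbered 4 passed 0.1, and the rule set beforehand asked this of every pair, so the numbers were not taken to pair the samples as a whole; 5 of 10 libraries correlated best with their own number. A block over all RNA libraries was not run, since the numbers in the RP columns did not match those in the sample titles. Pairing of RP libraries by their column numbers was not tested.

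Shared calls of Dnmt3aKO and Tet2KO effects in HSCs were 141 with no filter, 54 with DESeq2, 2 without the libraries numbered 4, and 0 to 1 leaving out 1 library; their correlation ranged from 0.387 (without Dnmt3aKO HSC replicate 2) to 0.69 (without Control HSC replicate 3). Shared Tet2KO calls in HSCs and RPs were 92 with no filter, 68 with DESeq2, and 14 (without Control HSC replicate 3) to 27 leaving out 1 library. Their correlation was 0.113 with no filter, 0.266 without the libraries numbered 4, and 0.237 to 0.312 leaving out 1 library.

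Adjusted camera p-values of the lists follow; those in Tet2KO RPs carry the selection of each list. With an estimated correlation they were 0.189 for both lists in Dnmt3aKO HSCs, 0.348 for both in Tet2KO HSCs and 0.14 for the RP-high list from Control cells in Tet2KO RPs. Without the libraries numbered 4, at the preset correlation, both lists kept their calls in Dnmt3aKO HSCs (9.81e-07 and 0.0262) and in Tet2KO HSCs (0.0128 and 0.0478). In Tet2KO HSCs the RP-high list reached 0.797 with 500 transcripts. In Tet2KO RPs the HSC-high list from Tet2KO cells reversed camera's direction with 100 transcripts (0.966) and passed the threshold without the libraries numbered 4 (0.026). Leaving out 1 library, the RP-high and HSC-high lists ranged from 5.77e-12 to 0.0718 and from 1.03e-05 to 0.563 in Dnmt3aKO HSCs, and from 5.81e-06 to 0.955 and from 8.24e-05 to 0.955 in Tet2KO HSCs. There the RP-high call was lost without Control HSC 3 (0.117), Tet2KO 2 (0.127), Tet2KO 3 (0.198) and, reversed, Control 4, and the HSC-high call without Tet2KO 3 (0.623) and Control 4. In Tet2KO RPs, with lists from Tet2KO cells, they ranged from 0.016 (Control RP d) to 0.891 and from 0.00408 (Control RP c) to 0.917 (Control RP d, reversed). Camera's direction of the RP-high list reversed without Tet2KO RP b (0.531) and Control RP c (0.828), and its median, -0.02, rose above 0 without Control RP a, Control RP c and Tet2KO RP a. The HSC-high list passed without Tet2KO RP a (0.0207), b (0.007) and c (0.00863).

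Of 296 alternatives for named transcripts, 253 kept the call and 43 lost it, with no reversal. Not counted are fits in which the filter or DESeq2 gave no test: 4 for ENSMUST00000103446.1 (only the groups compared; without Tet2KO RP b, c or d) and 3 for ENSMUST00000103558.2 (DESeq2; only the groups compared; without Tet2KO RP d). The highest-count transcript per gene, the gene lists, and Dnmt3a and Tet2 levels were not run, because the sources used here do not pair identifiers with genes.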

Other observations

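The test without the 100 most counted transcripts and the test of transcripts with at least 20 counts were set before their results were seen; the rest were chosen after. Tet2KO fold changes depended on abundance. Transcripts were ranked by mean level into 5 bins of 5364. In the lowest bin the median log2 fold change was 0.65 in Tet2KO HSCs and 0.28 in Tet2KO RPs, and in the highest bin it was -0.09 and -0.10. In Dnmt3aKO HSCs the medians were 0.01 in both bins. The filter and the bins used the same libraries, and both Tet2KO groups held more transcripts on average at equal depth. The trend with abundance therefore cannot be told apart from that difference in detection.

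Tet2KO RPs held 2669 more transcripts than Control RPs at equal depth, a difference that missed the threshold after adjustment (exact permutation p = 0.0286, adjusted 0.0857). Without the 100 most counted transcripts of each library the difference was 2701, which argues against a few transcripts taking the counts. The 25 transcripts called higher are too few to make up the difference. Changes below the threshold, or in transcripts removed by the filter, were not counted. In simulated Tet2KO RPs the count test recovered 18 of 100 transcripts changed 4-fold, so the number of calls cannot decide this. Restricted to transcripts with at least 20 counts, the difference was 896 (exact permutation p = 0.0571), and with at least 5 counts 1898 (exact permutation p = 0.0571). In percent of Control RPs it was no smaller there, at 6.55% for 1 count, 8.523% for 5 and 7.936% for 20. The p-values miss the threshold, so the difference cannot be told apart from a gain in transcripts with very few counts. Tet2 loss and a difference in library complexity both remain open.

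The simulated spread of fold changes was close to the observed one for Tet2KO over Control RPs (variance 0.766 against 0.856) and far below it for both HSC comparisons (1.10 against 2.15, and 0.922 against 2.47).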
